A study of Homo sapiens with 12 samples.

How the data were processed

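Messenger RNA of THP-1 cells was measured on 12 Affymetrix PrimeView Human arrays, per the labels' protocols, with biotin-labelled total RNA extracted with Trizol and arrays run by a service centre. Titles and treatment labels put 3 arrays in each of 4 groups: cells at 37 °C, cells at 40 °C, control cells and cells labelled siThermomir. The treatment protocol describes hairpin microRNA inhibitors against miR-142, miR-143 or ThermoMIR-1 and a non-human control, whereas the titles say siRNA and WT, so the group is called thermomiR inhibitor without naming a target. The growth protocol gives harvests at 2, 8 and 24 hours at 40 °C, and which of them the arrays come from is not stated. The deposited table holds log2 expression values of 49395 probe sets on all 12 arrays. The unit was read from the values (2 decimals and closely similar distributions, with array medians of 5.72 to 5.87). The background correction, normalization, summarisation, software and genome build that the authors used are not given in the sources used here. The 2 experiments differ in handling (nucleofection and sorting), so each was tested alone.

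Probe sets were named through the platform's gene table. Of the 49395, 44994 have 1 gene symbol, 1832 have several and 2473 that are not controls have none here. There are 102 control probe sets, a few of which have a symbol and are counted among the former. Genes were represented by the probe set with the highest mean over all 12 arrays among those with exactly 1 symbol. Of 18132 genes, the 13909 whose mean reached the 30th percentile of all probe sets that are not controls (log2 4.48) were tested, and 10002 of these have more than 1 probe set. Entrez numbers matched a current gene table for 18112 symbols, none of which differed. No genome or transcripts were used, so no coordinates are given and the planned comparison of genes with and without microRNA seed matches in their 3 prime UTR was not run.

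Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the deposited log2 values without a block, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Residual degrees of freedom were 4, with prior degrees of freedom of 3.86 for temperature and 3.33 for the inhibitor. For 3 arrays against 3, the smallest p that an exact permutation test can give is 0.1, so no such test was run per gene. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested, with an estimated correlation and the fry test beside it. The 29 lists hold 514 genes, of which 472 have a probe set of 1 symbol and 445 were tested. The cold-inducible list has 2 genes and no list test. Folds are ratios on the linear scale computed from differences of mean log2 values, and errors are SDs over the 3 arrays of a group or SEs of the fit.

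Groups, designs, alternatives, lists and the rule for named genes were fixed before the data were examined. Per comparison the rule takes the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap, up to 4 members of each called list by p, a fixed set of heat shock, cold, cytokine and macrophage genes, and up to 6 genes called in both experiments by the smaller of their differences. HSPA1A, in the fixed set, has no probe set of 1 symbol. Alternatives were a joint fit of all 12 arrays, the replicate number as a block, no filter or a 50th percentile filter, the mean of a gene's probe sets, every probe set on its own, quantile normalization, centring on the median, eBayes with trend and robust, array weights, leaving out each array, and an estimated correlation for lists. A covariate for the poly-A spike level was added after seeing the data.

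The procedure was tested on simulated data made from the real means and residual SDs of the 13909 genes, with 200 genes changed. For temperature, 38% of 50 genes changed by 0.25 on the log2 scale were recovered, 84% at 0.5, and all at 1 and 2, with 8 false calls among 169. For the inhibitor comparison the shares were 6%, 58%, 96% and 98%, with 1 false call among 130. A list shifted by 0.5 was called in each comparison, and none of the other 27. The genes were simulated independently of each other, so this does not test false list calls where genes of a list vary together. Figures were drawn with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. Some genes of the lists are not analysed here.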

Results

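Messenger RNA was measured on 12 PrimeView arrays of THP-1, a human monocytic leukaemia line that takes on a macrophage-like state when treated with the phorbol ester PMA. The arrays form 4 groups of 3. Cells of the temperature experiment were kept at 37 °C or at the fever-like temperature of 40 °C after differentiation with 100 ng/ml PMA for 48 hours. In the other experiment, cells given an inhibitor of a thermomiR (a temperature-responsive microRNA) were compared with control cells. The protocol in the labels has these cells differentiated at 40 °C, nucleofected with a hairpin inhibitor and a GFP plasmid, and sorted for GFP 24 hours later. Which microRNA was blocked is not stated for the arrays, and the controls are labelled only as wild type and control. The arrays do not measure the microRNAs themselves. Array medians lay between 5.72 and 5.87 on the log2 scale. Arrays of 1 group correlated at r = 0.9935 to 0.9985 across probe sets, against 0.9888 to 0.9902 between temperatures and 0.9703 to 0.9783 between inhibitor and control. No label says that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical. With 3 arrays in each group, the number of arrays limits the precision.

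The first comparison asked which transcripts differ in macrophage-like cells at fever-like temperature. The largest decreases were in transcripts of cold-inducible RNA-binding proteins, both of which fell. RBM3, whose product binds RNA and is induced by mild cold, was 14.5-fold lower at 40 °C, with log2 levels of 8.32 ± 0.13 against 12.17 ± 0.09 (SD, n = 3 each). CIRBP, a related cold-induced protein, was 3.89-fold lower, at 8.98 ± 0.05 against 10.94 ± 0.01. A fainter probe set of each gene was not called, at −0.06 for RBM3 and −0.22 for CIRBP. Cytosolic chaperone transcripts rose: HSPA4L was 3.38-fold and HSPH1 2.07-fold higher, and DNAJB1 was higher by 1.07 on the log2 scale. The chemokine gene CXCL8 was 3.00-fold lower, at 5.52 ± 0.25 against 7.10 ± 0.09. In all, 3007 of 13909 genes were higher and 2465 lower at 40 °C (limma, Benjamini-Hochberg adjusted p under 0.05), of which 73 and 68 differed by at least 2-fold. The groups did not overlap for 6880 genes, 49.5% of those tested, where chance gives 10%. For 323 of the called genes, another probe set of the gene was called in the opposite direction.

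**Figure D1:**
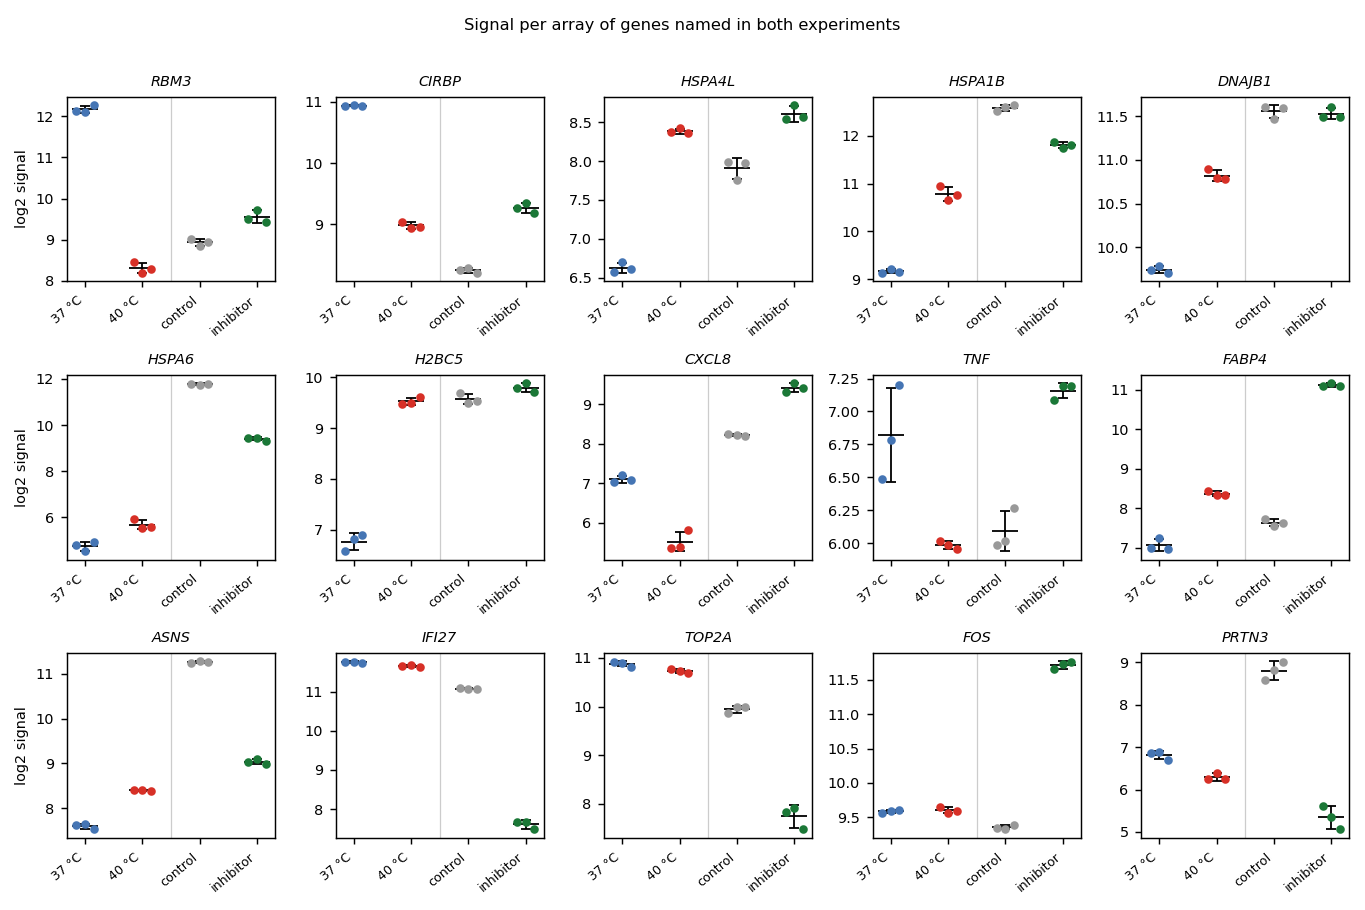
Log2 signal of 15 named genes on each array (points), with the group mean and SD (bars, n = 3), for the temperature experiment on the left of each panel and the inhibitor experiment on the right. RBM3 lies at 12.17 at 37 °C and 8.32 at 40 °C, FABP4 at 7.63 in controls and 11.11 with the inhibitor, and each panel has its own vertical scale.

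Heat shock chaperones had the largest share of higher members among the lists tested. Of 25 measured members of the cytosolic list, 21 rose and none fell (22 adjusted over the list alone), with a median log2 difference of 0.67 (camera, adjusted p = 1.55e-11). With an estimated correlation between genes the adjusted p was 0.164. Despite its name the list also holds HSPD1 and HSPE1, chaperonins of mitochondria, and SERPINH1 of the endoplasmic reticulum. The inducible HSP70 transcript HSPA1B was 3.06-fold higher, but its near-identical copy HSPA1A has no probe set of its own here, so the value is uncertain as to which copy was measured. HSPA6, an HSP70 form expressed mainly under stress, was 1.91-fold higher (log2 5.68 ± 0.20 against 4.74 ± 0.19). BAG3, a co-chaperone of HSP70, was 1.73-fold, HSP90AA1 1.36-fold and the constitutive HSPA8 1.12-fold higher. The HSPA8 call was lost without replicate 1 at 37 °C (log2 difference 0.15) and without replicate 3 at 40 °C (0.15), 1 of its 9 probe sets was called lower, and the mean of its probe sets was not called (0.05). Of the 8 subunits of TRiC, a chaperonin that folds actin and tubulin, 6 rose (6 adjusted over the list alone; adjusted p = 0.0193, and 0.248 with an estimated correlation), among them CCT3 by 1.42-fold, CCT6A by 1.27-fold, CCT7 by 1.25-fold and CCT5 by 1.18-fold. The endoplasmic reticulum chaperone HSPA5 differed by 0.04 (SE 0.04) and did not pass the test.

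Transcripts of the ATF4 stress programme also rose as a list, with 10 of 17 higher and 1 lower (the same counts adjusted over the list alone; adjusted p = 0.000896, and 0.243 with an estimated correlation). The members with the smallest p were PHGDH (2.36-fold) and PSAT1 (1.82-fold), enzymes of serine synthesis, CEBPB (1.94-fold), a transcription factor, and ASNS (1.75-fold), which makes asparagine. DDIT3, the stress-induced factor CHOP, differed by 0.01 (SE 0.06) and was not called. Of 17 DNA replication genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 0.000217, and 0.306 with an estimated correlation). GINS2 was 1.58-fold, MCM3 1.51-fold, MCM2 1.41-fold and MCM6 1.34-fold higher, although another MCM6 probe set was called lower and the mean of its probe sets was not called (0.05). MKI67, a marker of dividing cells, differed by 0.10 (SE 0.05) and was not called.

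Macrophage genes moved mostly upward, with 15 of 20 higher and 4 lower (the same counts adjusted over the list alone; adjusted p = 0.00111, and 0.248 with an estimated correlation). CD163, a scavenger receptor, was 1.95-fold, the lipase LPL 1.68-fold, and the lysosomal proteases CTSD and CTSL 1.54-fold and 1.49-fold higher. CSF1R, CD14 and CD68 were 1.24-fold, 1.18-fold and 1.17-fold higher. The CD68 call was lost without replicate 1 at 37 °C, with an adjusted p of 0.0516. Markers of promyelocytes and neutrophils fell, with 6 of 9 lower and 1 higher (7 lower adjusted over the list alone). The camera adjusted p was 0.00403, and 0.243 with an estimated correlation. S100A9 was 2.05-fold, ELANE 1.79-fold, PRTN3 1.44-fold and CTSG 1.35-fold lower. Metallothioneins, small metal-binding proteins, fell in 5 of 8 members (5 adjusted over the list alone; adjusted p = 0.00403, and 0.248 with an estimated correlation), by 2.24-fold for MT1F, 1.66-fold for MT2A and for MT1X, and 1.63-fold for MT1E. Splicing factor transcripts were lower in 12 of 19 and higher in 2 (13 lower adjusted over the list alone; adjusted p = 0.000444, and 0.254 with an estimated correlation). SRSF5 was 1.87-fold, SRSF6 1.79-fold and CLK4 1.32-fold lower, and SRSF4 was 1.29-fold higher. The other SRSF6 probe set did not go down.

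The inflammatory list had members on both sides. Besides CXCL8, TNF was 1.78-fold lower (log2 5.99 ± 0.03 against 6.82 ± 0.36), PTGS2, the inducible enzyme of prostaglandin synthesis, 1.65-fold lower and IL1B 1.36-fold lower. IL6 and IL6ST differed by 0.05 (SE 0.14) and 0.003 (SE 0.06) and were not called, whereas the receptor TLR2 was 1.20-fold higher. The list of NF-kB targets had 3 members higher and 7 lower of 21 and did not pass (adjusted p = 0.366; median 0.01, mean −0.15). Among the 10 largest increases were 3 histone genes, H2BC5 (6.74-fold), H2AC8 (3.82-fold) and H2AC6 (3.78-fold), besides BBOX1 (6.02-fold), SYT11 (3.78-fold), LDHAL6B (3.69-fold), FCGBP (3.66-fold), DYSF (3.43-fold) and MYOZ2 (3.26-fold). Histone probe sets may read several near-identical genes. The 37 °C means of BBOX1, SYT11 and LDHAL6B lay below the signal used as the filter. The other large decreases were SEMA3D (3.84-fold), CMAHP (3.76-fold), LONRF2 (3.73-fold), LRRK2 (3.43-fold), TNFSF18 (3.42-fold), the single-stranded RNA receptor TLR8 (3.31-fold) and CRYBG1 (3.00-fold), with SEMA3D and LRRK2 below the filter's signal at 40 °C.

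Of the 28 lists tested, 8 passed with the preset correlation of 0.01 and none with an estimated one. For markers of promyelocytes and neutrophils the estimated correlation was below 0 (−0.09), yet the unadjusted camera p rose from 0.000905 to 0.0261. Correlation between genes alone therefore does not account for the lost calls. With an estimated correlation, camera also takes its p from the 4 residual degrees of freedom, whereas with the preset one it does not. The larger p-values therefore also reflect the small number of arrays. The fry test, which asks whether a list's genes move 1 way on balance, gave the 8 lists adjusted p between 1.71e-05 and 0.000494. It does not compare a list with other genes, and it also called 10 of the other 20 lists, from endoplasmic reticulum chaperones (0.000596), NRF2 targets (0.00191) and NF-kB targets (0.00208) to cholesterol synthesis (0.0404), so it does not set the 8 apart. The other 20 lists did not pass camera, although with every probe set on its own NRF2 targets (adjusted p = 0.00554) and oxidative phosphorylation (0.0379) did. Higher and lower members were 7 and 2 of 20 for endoplasmic reticulum chaperones, 5 and 2 of 14 for NRF2 targets, 5 and 7 of 20 for fever signalling, 8 and 9 of 26 for interferon-stimulated genes, 3 and 2 of 16 for antigen presentation, and 3 and 2 of 14 for alternative activation. They were 2 and 6 of 18 for mitosis, 6 and 4 of 20 for glycolysis, 4 and 3 of 13 for cholesterol synthesis, 7 and 3 of 13 for LXR targets, 2 and 5 of 22 for oxidative phosphorylation, and 1 and 0 of 20 for ribosomal proteins. They were 5 and 3 of 16 for microRNA processing, 6 and 3 of 18 for autophagy, 8 and 3 of 18 for apoptosis, and 3 and 3 of 16 for immediate early genes. Markers of other cell types had 0 and 0 of 6 for erythroid cells, 1 and 0 of 7 for lymphocytes, and 1 and 1 of 8 for fibroblasts and epithelium. Median and test differed in sign for the NF-kB, fever, alternative activation and cholesterol lists (medians 0.01, 0.01, 0.01 and −0.003). The fever list had a mean of −0.06, and the fibroblast and epithelial list a mean of 0.02 with a median of −0.02.

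**Figure D2:**
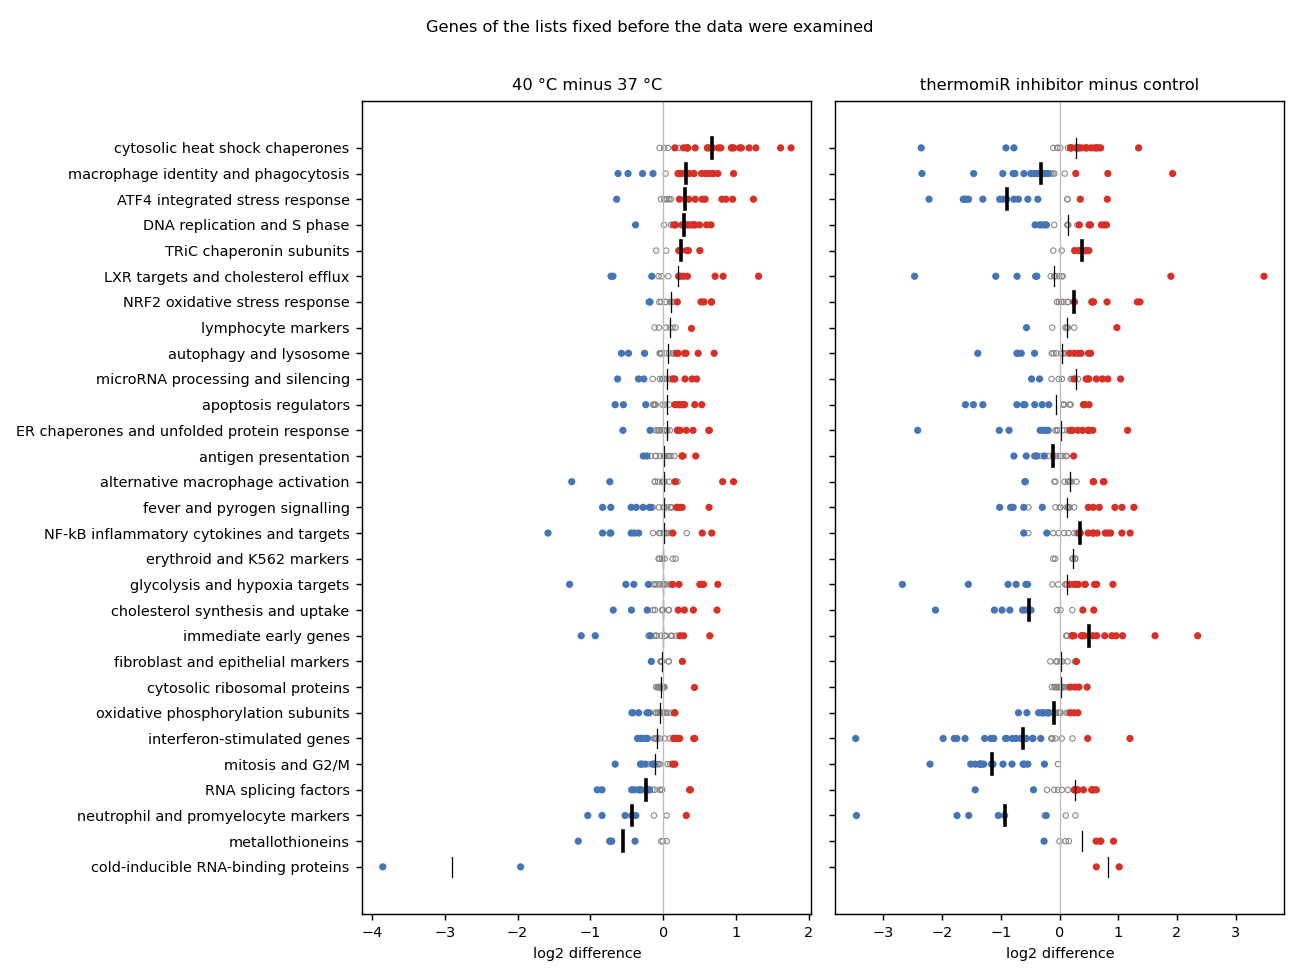
Log2 differences of the members of 29 gene lists in the temperature experiment (left) and the inhibitor experiment (right). Filled points passed the test (red higher, blue lower), open points did not, and vertical bars are list medians, thick where camera called the list; chaperones lie highest at 40 °C (median 0.67) and mitosis genes lowest with the inhibitor (median −1.15).

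The second comparison asked what changes when a thermomiR is blocked in cells differentiated at 40 °C. Whether the control cells received the control inhibitor is not stated, so the groups may also differ in handling. The inhibitor arrays had lower transcripts of many interferon, granule and cell division genes. FABP4, a fatty acid binding protein, was 11.2-fold higher, at 11.11 ± 0.04 against 7.63 ± 0.09 in controls (SD, n = 3 each), and PLIN2, a coat protein of lipid droplets, 3.72-fold higher. IFI27, an interferon-induced gene, was 11.1-fold lower (7.61 ± 0.11 against 11.08 ± 0.02), and the topoisomerase gene TOP2A 4.62-fold lower. The granule protease gene PRTN3 differed by −3.46 on the log2 scale (5.34 ± 0.28 against 8.80 ± 0.22). Of 13909 genes, 3567 were higher and 2721 lower (limma, adjusted p under 0.05), with 95 and 376 of them at least 2-fold apart. The groups did not overlap for 7525 genes (54.1%, where chance gives 10%), and for 404 called genes another probe set was called in the opposite direction. The groups also differed in control probe sets: the poly-A spikes, bacterial RNAs added to each sample before labelling, were 2.56-fold lower with the inhibitor (log2 5.87 ± 0.32 against 7.22 ± 0.37), and 18S rRNA signal was 6.09-fold lower, while the 28S middle probe set was 1.26-fold higher. With the spike level of each array as a covariate, chosen after seeing the data, 59 genes were called higher and 188 lower. The median size of the differences of called genes was 0.42 without and 0.43 with it, while their median SE rose from 0.07 to 0.20.

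Cell division genes gave the clearest list. Of 18 mitosis genes, 17 fell and none rose (17 adjusted over the list alone), with a median of −1.15 (camera, adjusted p = 5.39e-12, and 0.188 with an estimated correlation). Besides TOP2A, BUB1 was 2.85-fold, CDK1 2.50-fold and KIF11 2.45-fold lower, and MKI67 was 1.54-fold lower. DNA replication genes went both ways, 6 higher and 5 lower of 17, and were not called as a list (adjusted p = 0.718). Interferon-stimulated genes fell in 18 of 26 and rose in 2 (the same counts adjusted over the list alone; adjusted p = 2.51e-08, and 0.234 with an estimated correlation), among them IFI44L by 3.95-fold, IFI44 by 3.47-fold and the transcription factor IRF7 by 3.36-fold. Antigen presentation genes fell in 5 of 16 and rose in 1 (the same counts adjusted over the list alone; adjusted p = 0.0244, and 0.188 with an estimated correlation). PSMB9 and PSMB8, subunits of the immunoproteasome, were 1.71-fold and 1.31-fold lower, the peptide transporter TAP2 1.48-fold lower. HLA-DMA was called lower, but its signal lay below that of the filter in both groups (3.73 ± 0.11 against 4.15 ± 0.18). The list's call was lost without replicate 2 of the inhibitor arrays (adjusted p = 0.069) and with the spike covariate (0.0722), and the HLA-DMA call without replicate 1 (log2 difference −0.38).

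Stress genes divided. ATF4 targets fell in 13 of 17 and rose in 2 (the same counts adjusted over the list alone; adjusted p = 1.96e-06, and 0.188 with an estimated correlation), with ASNS 4.67-fold, TRIB3 3.07-fold, SESN2 3.02-fold and PHGDH 2.93-fold lower and DDIT3 1.87-fold lower. HSPA6 was 5.12-fold lower, at 9.41 ± 0.07 against 11.77 ± 0.04. The HSPA1B signal, which may include HSPA1A, was also lower, at 11.80 ± 0.06 against 12.58 ± 0.06. The cytosolic chaperones had 16 members higher and 3 lower of 25 (18 and 3 adjusted over the list alone) and did not pass as a list (adjusted p = 0.0532). It passed without replicate 3 of the controls (0.0477), and without replicate 1 (0.0434) or 3 (0.0499) of the inhibitor arrays. It also passed with all 12 arrays in 1 fit, trend and robust eBayes, every probe set, no filter, the 50th percentile filter, quantile normalization or centring (adjusted p from 0.00646 to 0.0485), but not with an estimated correlation (0.392) or the spike covariate (0.105). HSPH1 and DNAJB1 differed by 0.01 (SE 0.07) and −0.03 (SE 0.07) and were not called, although the mean of the DNAJB1 probe sets was lower by more and called (−0.73). HSP90AA1 was 1.15-fold, BAG3 1.21-fold and HSPA8 1.15-fold higher, but 4 of the 9 HSPA8 probe sets were called lower and their mean differed by −1.38 on the log2 scale. HSPA5 was 1.17-fold lower. With the replicate number as a block none of these 4 passed (adjusted p = 0.108 for HSP90AA1, 0.0584 for BAG3, 0.101 for HSPA8 and 0.0714 for HSPA5). TRiC subunits rose in 6 of 8 (6 adjusted over the list alone; adjusted p = 0.0322, and 0.289 with an estimated correlation), with CCT7 1.41-fold, CCT6A and CCT2 1.39-fold and TCP1 1.35-fold higher. The TRiC call was lost with the replicate number as a block (adjusted p = 0.0561), with array weights (0.0619) and with the spike covariate (0.0973). Genes of the NRF2 response to oxidants rose in 8 of 14 and fell in none (8 adjusted over the list alone; adjusted p = 0.00783, and 0.284 with an estimated correlation), with SRXN1 2.58-fold, NQO1 2.51-fold, TXNRD1 1.75-fold and TALDO1 1.46-fold higher. The cold-inducible genes were higher with the inhibitor, CIRBP by 2.02-fold and RBM3 by 1.54-fold. The fainter RBM3 probe set differed by −0.01 (SE 0.11).

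Immediate early genes, which respond to signals within minutes, rose in 14 of 16 (15 adjusted over the list alone; adjusted p = 5.9e-06, and 0.188 with an estimated correlation), with FOS 5.11-fold, NR4A1 3.09-fold and IER2 1.95-fold higher, and ZFP36 higher by 1.07 on the log2 scale. NF-kB targets were higher in 11 of 21 and lower in 2 (11 and 3 adjusted over the list alone; adjusted p = 0.0265, and 0.392 with an estimated correlation). CXCL8 was 2.30-fold, TNF 2.09-fold, NFKBIZ 1.83-fold and CCL20 1.72-fold higher, TLR2 was 1.92-fold higher, and IL1B was 1.53-fold lower. IL6, IL6ST and PTGS2 differed by 0.25 (SE 0.13), 0.14 (SE 0.07) and −0.53 (SE 0.20) and were not called. PTGS2 passed without replicate 2 of the controls (−0.65) or replicate 2 of the inhibitor arrays (−0.68), and with the 50th percentile filter, all 12 arrays in 1 fit, array weights, centring, trend and robust eBayes or the mean of probe sets (adjusted p from 0.00408 to 0.0467). IL6 passed with array weights (0.0244). For IL6ST 3 of 8 probe sets were called lower, and it was called lower with the mean of probe sets (−0.44) and higher with quantile normalization (0.19).

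Macrophage genes fell in 13 of 20 and rose in 3 (14 and 3 adjusted over the list alone; adjusted p = 0.000428, and 0.188 with an estimated correlation). LYZ, which encodes lysozyme, was 5.07-fold, the Fc receptor FCGR1A 2.76-fold and the lipid carrier APOE 1.95-fold lower, whereas the protease MMP9 was 3.80-fold higher. CD14 was 1.73-fold and CD68 1.40-fold lower, and CSF1R was 1.21-fold higher, with 1 of its 3 probe sets called lower and their mean at −0.19. The CSF1R call was lost with the replicate number as a block (adjusted p = 0.0524). Markers of promyelocytes and neutrophils fell in 6 of 9 and rose in none (6 adjusted over the list alone). The camera adjusted p was 0.000867, and 0.188 with an estimated correlation. ELANE was 3.36-fold, AZU1 2.92-fold and CTSG 2.06-fold lower. Cholesterol synthesis genes fell in 8 of 13 and rose in 2 (8 and 3 adjusted over the list alone; adjusted p = 0.00487, and 0.188 with an estimated correlation). STARD4, which carries sterols, was 4.33-fold, SC5D 2.16-fold and MSMO1 1.80-fold lower, and the enzyme gene SQLE was 1.50-fold higher. Subunits of oxidative phosphorylation fell in 9 of 22 and rose in 3 (the same counts adjusted over the list alone; adjusted p = 0.0499, and 0.566 with an estimated correlation). COX5B was 1.62-fold, NDUFS3 1.47-fold and NDUFB5 1.28-fold lower and SDHA 1.24-fold higher. That list did not pass without replicate 1 of the controls (0.0671) or replicate 1 of the inhibitor arrays (0.0673), nor with the 50th percentile filter (0.0866), the mean of probe sets (0.0707), quantile normalization (0.071), the replicate number as a block (0.0652) or the spike covariate (0.0606).

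Other large increases were PDK4 (6.92-fold), a kinase that restrains glucose oxidation, CGA (6.28-fold), the interleukin receptor IL7R (4.98-fold), HINT3 (4.45-fold), FLJ42393 (3.73-fold) and HGD (3.56-fold). PDK4 and CGA lay below the filter's signal in controls, and the other HINT3 probe set was called lower. Other large decreases were MNDA (log2 difference −3.46, below the filter's signal with the inhibitor), MLPH (8.90-fold), the protease CTSZ (7.98-fold), THBS2 (7.69-fold), PPP1R27 (7.01-fold), FBP1 (6.53-fold), an enzyme of glucose synthesis, PKM (6.39-fold) and CLEC2B (6.38-fold). Of 6 PKM probe sets only 2 went down, and 1 was called higher. For MLPH 4 of 7 and for CLEC2B 1 of 2 probe sets went down.

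In all, 12 of the 28 lists passed with the preset correlation and none with an estimated one. Other splits of the 6 arrays, which mix the 2 groups, called 0 genes but up to 10 lists at the preset correlation. The number of lists called therefore says little by itself. Fry gave the 12 lists adjusted p between 4.27e-05 and 0.0098. Fry also called 11 of the other 16 lists, from metallothioneins (0.00254), microRNA processing (0.00344) and fever signalling (0.00394) to splicing factors (0.036), and cytosolic chaperones (0.00553) among them. Among lists that did not pass camera, higher and lower members were 8 and 7 of 20 for endoplasmic reticulum chaperones, 6 and 5 of 20 for fever signalling, 4 and 2 of 14 for alternative activation, 9 and 6 of 20 for glycolysis, and 2 and 5 of 13 for LXR targets. They were 4 and 0 of 20 for ribosomal proteins, 8 and 2 of 16 for microRNA processing, 11 and 2 of 19 for splicing factors, 6 and 5 of 18 for autophagy, 4 and 9 of 18 for apoptosis, and 4 and 1 of 8 for metallothioneins. MicroRNA processing passed with trend and robust eBayes (0.0376), every probe set (0.0193) and without replicate 3 of the controls (0.0477), and splicing factors with the former 2 settings (0.0372 and 0.0162) and without replicate 1 of the inhibitor arrays (0.0493). Apoptosis genes passed with the mean of probe sets (0.0087), no filter (0.0228) and the spike covariate (0.0204). With every probe set, metallothioneins (0.0166), LXR targets (0.0162), DNA replication genes (0.0288) and autophagy genes (0.0437) passed too. Markers of other cell types had 0 and 0 of 6 for erythroid cells, 1 and 1 of 7 for lymphocytes, and 1 and 0 of 8 for fibroblasts and epithelium. The median was above 0 and the mean below it for endoplasmic reticulum chaperones (0.02 and −0.07), glycolysis (0.12 and −0.14) and autophagy (0.04 and −0.10). For LXR targets the median was −0.09 and the mean 0.01. That list also covers cholesterol efflux, and its 2 higher members were FABP4 and PLIN2 (log2 differences 3.48 and 1.90), against 5 lower. Both are treated below as targets of PPAR receptors, so the list does not read LXR targets alone.

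**Figure D3:**
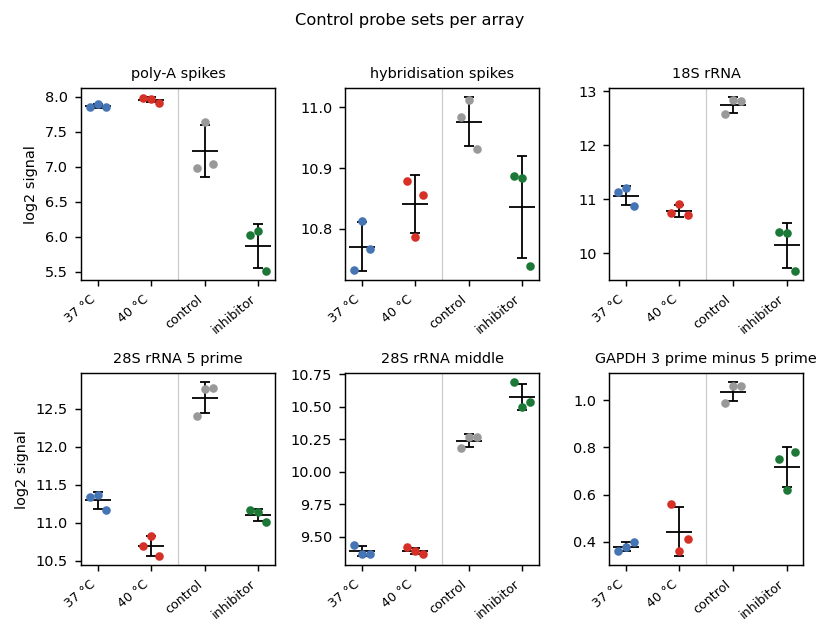
Log2 signal of control probe sets on each array (points), with group mean and SD (bars, n = 3); the lower right panel is a difference of 2 probe sets of GAPDH. Poly-A spikes lie at 7.22 in controls and 5.87 with the inhibitor, and 18S rRNA at 12.75 and 10.14.

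The third comparison asked whether genes that differ with temperature also differ with the inhibitor. Among the genes called in both experiments, the 6 with the largest smaller difference went different ways. FABP4 was 2.48-fold higher at 40 °C and 11.2-fold higher with the inhibitor, and ABCC3, a transporter, 2.72-fold and 3.00-fold higher. LOXL4 was 2.46-fold lower at 40 °C and 2.57-fold lower with the inhibitor, where only 1 of its 2 probe sets went down. RAB20, BHLHE41 and MYOZ2 were 2.79-fold, 2.61-fold and 3.26-fold higher at 40 °C but 3.94-fold, 6.26-fold and 2.91-fold lower with the inhibitor. LOXL4 and MYOZ2 lay below the filter's signal with the inhibitor. Of 3163 genes called in both, 60.5% had the same direction. Genes higher in both numbered 1076, where independent lists give 771, and genes lower in both 837, where they give 482. Genes higher at 40 °C and lower with the inhibitor numbered 688 (588 for independent lists), and the opposite combination was rarer than the 632 of independent lists (odds ratio 0.829). Fisher's exact test gave p = 1.28e-44, 6.68e-79, 3.52e-07 and 0.000336 for these overlaps in that order, across genes, which are not independent replicates. Across 13909 genes the log2 differences correlated weakly (Pearson r = 0.1003, Spearman rho = 0.108). The 2 experiments share no array.

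As sets, the heat-responsive genes did not pass limma's fry test (two-sided, threshold 0.05) in the inhibitor arrays. The 3007 genes higher at 40 °C had a mean log2 difference of 0.03 with the inhibitor and a median of 0.07, below the median of 0.09 over all 13909 genes, and 5 of the 10 splits of those arrays gave a mean at least as large in size. With an array left out this mean ranged from 0.0078 to 0.0546, both reached by leaving out an inhibitor array. The 2465 genes lower at 40 °C had a mean of −0.12, reached by 1 of the 10 splits, the real one. The latter set passed without replicate 2 of the inhibitor arrays (mean −0.15) and without replicate 3 at 40 °C (−0.13), and also with all 12 arrays in 1 fit, the mean of probe sets, quantile normalization, centring or array weights. The former set passed with quantile normalization alone (0.07).

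**Figure D4:**
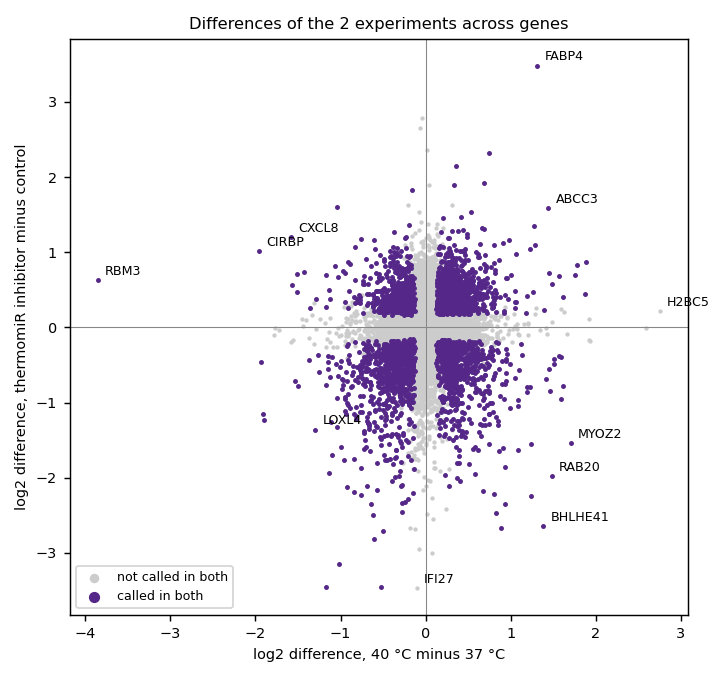
Each point is 1 of 13909 genes, with its log2 difference between 40 °C and 37 °C (horizontal) and between thermomiR inhibitor and control (vertical). The 3163 genes called in both are purple, and RBM3 and CIRBP lie at −3.85 and −1.96 with temperature and at 0.63 and 1.02 with the inhibitor.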

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

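The 3 prime bias test and the spike covariate were chosen after the results were seen. Probe sets outside the gene comparisons also carried differences. In the inhibitor arrays, compared with their controls, 18S rRNA signal was lower by 2.61 on the log2 scale (10.14 ± 0.41 against 12.75 ± 0.14, a difference of −2.61), the 28S rRNA 5 prime probe set differed by −1.54, and the poly-A spikes by −1.36, with all 12 spike probe sets called lower. At 40 °C the 28S rRNA 5 prime probe set differed by −0.60 from 37 °C. Another 2825 probe sets had enough signal but either no gene symbol or several. Of these, 536 were higher and 468 lower at 40 °C, and 623 were higher and 557 lower with the inhibitor.

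The many gene differences with the inhibitor stand beside those lower spike, 18S and 28S 5 prime signals, although the 28S middle probe set was higher (0.34) and the 3 prime one not called (0.05), so RNA input or labelling may account for part of them, in which case the way a gene follows the spikes among arrays of the same group should predict its difference between groups. Across called genes that correlation was r = 0.077, and with an array left out it ranged from −0.10 to 0.22, so it decides nothing. With the spike level as a covariate, 99.1% of the 6288 called genes had the same direction and a median size of 0.43 against 0.42, but the calls dropped to 59 higher and 188 lower because the median SE rose from 0.07 to 0.20, while 10 lists stayed or became called, among them mitosis (median −1.13, adjusted p = 1.58e-13), interferon (−0.64, 1.5e-08) and immediate early genes (0.60, 1.4e-06), and TRiC, antigen presentation and oxidative phosphorylation did not pass. More 3 prime bias in 1 group would move GAPDH and ACTB alike, yet the 3 prime minus 5 prime signal differed by −0.32 for GAPDH and by 0.26 for ACTB. A response to the blocked microRNA, the difference the design names, and these technical differences cannot be told apart with spikes that do not overlap between the groups. A difference in handling cannot be told apart either, since it is not stated whether the control cells received the control inhibitor.

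With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For temperature 1 of the 10 splits, the real one, gave as many as 5472 called genes, and the highest other gave 0 (limma; 6484 genes had an unadjusted p under 0.05 in the real split). For the inhibitor 1 of 10 gave as many as 6288, and the highest other gave 0. The counts of called lists, 8 and 12, were also reached by 1 of 10 splits, with 3 and 10 lists in the highest other. For genes higher at 40 °C, 5 of the 10 splits of the inhibitor arrays gave a mean of at least 0.03 in size, up to 0.06, and for genes lower at 40 °C 1 of 10 reached 0.12, with 0.11 the highest other.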

How the results depend on the processing

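The covariate for poly-A spikes was chosen after seeing the data, and the other alternatives were planned. Counts of called genes stayed within 1.5 times except under every probe set on its own (6823 higher and 6039 lower at 40 °C, 7355 and 7512 with the inhibitor, over 34507 probe sets in place of 13909 genes), array weights (5527 higher with the inhibitor) and the spike covariate (59 higher and 188 lower, where the SE rose). Estimated correlations left 0 lists called at 40 °C and 0 with the inhibitor, and every probe set gave 19 with the inhibitor. The replicate numbers gave no sign of pairing. Same-numbered deviations correlated at −0.13, −0.10 and 0.23 for temperature and −0.19, −0.60 and −0.15 for the inhibitor. Differently numbered ones reached 0.33 for temperature and 0.46 for the inhibitor. Deviations from the mean of so few arrays constrain each other, so these values cannot settle whether arrays were paired. The replicate block gave 2710 higher and 2245 lower genes and 8 lists at 40 °C, and 2581, 2199 and 10 with the inhibitor. With an array left out, counts ranged from 2443 to 2780 higher and 2037 to 2406 lower at 40 °C, and 2805 to 4025 and 2207 to 2935 with the inhibitor.

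Genes lower at 40 °C passed the fry test in the inhibitor arrays with all 12 arrays in 1 fit (−0.12), the mean of probe sets (−0.15), quantile normalization (−0.085), centring (−0.14) and array weights (−0.13). Over left-out arrays the mean ranged from −0.1516 to −0.0943, passing without inhibitor replicate 2 and without 40 °C replicate 3. Genes higher at 40 °C passed with quantile normalization (0.069) and had the opposite sign with every probe set (−0.035, not past the threshold). The cause was not tested. The correlation between experiments was 0.108 with the 50th percentile filter, 0.0942 without a filter, 0.106 with the mean of probe sets, 0.0473 with every probe set and 0.0925 with array weights, and 0.0833 to 0.111 with an array left out. With the mean of probe sets, 3 inhibitor results reversed: HSPA8 (−1.38), CSF1R (−0.19) and IL6ST (−0.44, called there, and called higher at 0.19 with quantile normalization). Their probe sets go in opposite directions. DNAJB1 gained a call there (−0.73).

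Among named genes, 2493 of 2531 values under alternatives kept their side of the threshold, 24 lost and 11 gained a call, and 3 reversed, leaving out the spike covariate, with which 247 of the 6288 inhibitor calls remained. Among lists, 855 of 888 kept theirs, 9 lost and 24 gained a call, leaving out the spike covariate and the estimated correlation. No list was called in the latter setting. HSP90AA1 with the inhibitor lost its call without every array but control replicate 2, HSPA8 without control replicates 1 and 3 and inhibitor replicate 1, BAG3 without control replicates 1 and 2, and HSPA5 without control replicate 1. Signs of results called in neither fit changed 55 times, at sizes up to 0.125. Signal near background limits genes below the filter, where folds are compressed.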

Other observations

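Gene families were read from symbols after the named genes had been seen, and the tests on S phase and on culture temperature were chosen after the values they rest on were seen. Of 24 tests on 12 families in both experiments, 3 passed with camera at the preset correlation and 0 with an estimated one. Histone genes rose at 40 °C, 15 of 32 higher and 1 lower (adjusted p = 0.000323, and 0.182 with an estimated correlation). Beyond the 3 named in the report, H1-2 was 3.08-fold, H4C8 2.81-fold, H2AC11 2.75-fold, H3C4 2.69-fold and H2BC21 2.31-fold higher, while the median of all 32 was 0.17 (0.15 with quantile normalization, 0.16 with centring). S100 calcium-binding proteins fell at 40 °C in 6 of 12 and rose in 1 (adjusted p = 0.0341, and 0.529 with an estimated correlation). S100A3 was 1.83-fold and S100A13 1.67-fold lower and S100A11 1.18-fold higher. Of the members, 2, S100A8 and S100A9, also sit in the list of promyelocyte and neutrophil markers. These genes were chosen after their values were seen.

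Cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, fell with the inhibitor in 12 of 19 and rose in 6 (adjusted p = 0.0184, and 0.855 with an estimated correlation), with medians of −0.50, −0.48 and −0.52 as deposited, with quantile normalization and with centring. CARS1 was 2.01-fold, WARS1 1.95-fold, EPRS1 1.87-fold and GARS1 1.75-fold lower, whereas VARS1 was 1.50-fold, HARS1 1.42-fold and FARSA 1.35-fold higher. WARS1 also belongs to the ATF4 list.

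Levels of the control cells can be set beside those at 40 °C only loosely, since handling differed and the normalization is unknown. RBM3 lay at 8.93 ± 0.08 in controls and 9.56 ± 0.15 with the inhibitor, against 8.32 ± 0.13 at 40 °C and 12.17 ± 0.09 at 37 °C (SD, n = 3 each), and CIRBP at 8.24 ± 0.04 and 9.26 ± 0.08 against 8.98 ± 0.05 and 10.94 ± 0.01. HSPA6 was at 11.77 ± 0.04 in controls and 5.68 ± 0.20 at 40 °C. These differences between experiments were not tested.

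The higher RBM3 and CIRBP with the inhibitor could come from cooler cultures. Were that the main difference between inhibitor and control cells, genes called at 40 °C would move the opposite way. Across 5470 such genes without RBM3 and CIRBP the differences correlated at r = 0.137 (0.129 to 0.139 for single inhibitor arrays, each set against the same control mean). These genes therefore did not move the opposite way on balance. A correlation over nearly the same genes was known when the test was chosen, so it cannot serve as an independent test of cooler culture. A temperature gap beneath other changes stays open, as does an effect of the blocked microRNA, which was not tested separately.

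Higher histone transcripts at 40 °C may partly reflect probe sets that read several paralogs. Probe sets made for 1 gene had a median of 0.11 with 39.1% of 23 called higher, against 0.26 and 61.5% of 26 for shared ones, which does not settle it. More cells in S phase remains possible, and the median of the replication genes was 167% of that of the histone genes. Both medians were known when this measure was chosen, so it cannot decide. The largest histone changes were far above any replication gene. An effect of temperature on histone transcripts apart from the cell cycle was not tested.

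FABP4, PDK4, PLIN2 and CPT1A (2.91-fold higher) are targets of the lipid-sensing PPAR receptors, so the hypothesis was tested that other PPAR targets rise with the inhibitor. Of 13 further targets tested, 5 were higher and 3 lower, with a median of 0.05 (camera of limma, a single test, unadjusted p = 0.789, and 0.857 with an estimated correlation). ACADVL was 1.89-fold and CD36 1.77-fold higher, and UCP2 1.78-fold lower. The data give no evidence that the targets beyond those 4 rise as a set.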
